A study of Rattus norvegicus with 8 samples.

How the data were processed

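Gene expression was measured in the soleus of female rats with 8 one-colour Affymetrix arrays. Each array received biotin-labelled cRNA made from 10 microg total RNA, and that RNA was a pool from 8 to 10 rats, per the labels. There were 3 arrays of control pools, 3 of unloaded pools and 2 of walked pools. The deposited values are signal intensity on a linear scale, 1 value per probe set, made with MAS5 per the submitters' processing notes. The MAS5 version and its scaling target are not given in the sources used here. MAS5 summarises the probe pairs of a set into a single signal after subtracting a mismatch or background estimate, so low signals are noisy and a fold change against a dim group is imprecise. The deposited intensity values had nearly the same trimmed mean on every array, between 148.4 and 148.8 after leaving out 2% at each end, which shows that the arrays had been scaled to one level before deposit.

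Each array was scaled to one 2% trimmed mean (148.6), values under the 10th percentile of all values (4.10) were set to that floor, and log2 was taken. Of 8740 probe sets, those under the 40th percentile of mean signal over all arrays (25.8) were left out, and 5244 were tested. The linear model of limma 3.58.1 in R 4.3.3 was fitted to all 8 arrays with the 3 groups as factor levels (lmFit, contrasts.fit and eBayes with a mean-variance trend, two-sided). The fit had 5 residual degrees of freedom and a prior of 6.00. P-values were adjusted over the tested probe sets by Benjamini-Hochberg, and a probe set is called, or said to have risen or fallen, where the adjusted p was under 0.05. A log2 fold change is followed by its standard error (SE) from the fit. Group means of signal are given with their SD. The number of arrays limits the precision: with 3 against 3 or 3 against 2 pools, the smallest exact permutation p is 0.1 for a single gene, so the calls rest on the spread pooled across genes.

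Gene symbols came from the platform annotation, joined through Entrez gene IDs to the gene table of rat assembly GRCr8. Of 8740 probe sets, 7006 carried 1 gene symbol, 308 carried several and 1426 are unnamed here. The gene table held 6985 of the 7006, and 0 symbols changed. No name was taken from a probe set with several genes. No coordinates are given, because no genome build belongs to the values. Counts of genes and all list tests use 1 probe set per gene, the one with the highest mean log2 signal, which gave 3154 genes. Of these, 892 had more than 1 tested probe set. Probe sets whose names carry a letter before the final part can match several transcripts. Among them are those that gave the values of Trim63 and Eif4a2.

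Before the data were examined, 28 gene lists that fit the tissue and treatment, including markers of other cell types in whole muscle, were fixed. Lists with at least 4 measured genes (27 of 28) were tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists within each comparison, and again with the correlation estimated from the data. Counts of list members use the adjustment over all tested probe sets and, beside it, the adjustment over the list alone. The genes named follow a rule also fixed before the data were examined: the 10 largest rises and 10 largest falls per comparison among called probe sets with no overlap between the arrays of the groups compared, up to 4 called members of each list by smallest p, and 20 measured genes of 24 fixed in advance. The other 4 fixed genes are not analysed here. A few genes outside this rule, chosen after their values were seen, complete short counts: Klf10, Decr1 and Lum in unloaded against control, and Rpl14 and Rpl13a in walked against control.

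The comparisons were unloaded against control, walked against unloaded and walked against control. The first 2 share the unloaded arrays and the first and last share the control arrays, so 100 simulations with no group differing gave the covariance that shared arrays alone produce. Simulations with no group differing and with walked equal to unloaded also gave the share of opposite signs among the 196 genes with the smallest p, a measure added after the data were seen. After that, the 3 shared arrays were also divided 1 and 2 in each of 6 ways, so that no array served both comparisons, and the signs of the 100 genes with the smallest p in the first were followed in the second. Alternatives were quantile normalization, the deposited values without rescaling, a higher floor and none, no filter and a stricter one, eBayes without a trend, fits with the 2 groups compared only, the pool number as a block, a minimum fold change of 1.5, each array left out in turn, estimated correlations for lists, and the mean over the probe sets of a gene. A fit on probe sets with a plain name ending was added after seeing the data. The signal ratios of control probe sets that had been intended as a check of RNA quality are not analysed here, so RNA quality was not compared between groups.

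The code was tested on simulated data with the means and spreads of the 5244 probe sets, in 20 runs with 200 changed probe sets each. At a 2-fold change it recovered 60.1% in unloaded against control, 53.9% in walked against unloaded and 54.5% in walked against control. At 1.5-fold these shares were 19.8%, 14.0% and 16.3%, and at 4-fold 91.8%, 90.8% and 89.5%. False calls made up 4.83%, 5.77% and 5.17% of all calls. Changes of 1.5-fold are therefore mostly missed at this number of arrays. The simulated noise was normal and independent between probe sets and arrays, with the spreads from the fit. The share of false calls therefore does not cover outlying arrays or errors shared by probe sets.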

Results

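Expression was measured in the soleus, a slow postural muscle of the hindlimb, after short changes in weight bearing. Control rats (3 pools) had 12 h of normal cage activity. Unloaded rats (3 pools) were kept off their hindlimbs for 12 h. Walked rats (2 pools) had the same 12 h of unloading and then 2 h of treadmill walking, in bouts of 30 min separated by 30 min in the cage over 4 h. Each pool held RNA of 8 to 10 rats, so p-values measure the spread between pools, not between rats. The median signal of the 8 arrays lay between 37.1 and 42.4 and the highest signal between 5942 and 8389. Correlation of log2 signal across tested probe sets was 0.949 to 0.963 within groups and 0.913 to 0.945 between groups. The first principal component held 28.0% of the variance and the second 25.01%. Control pool 3 stood apart from the other controls, at -30.0 on the first component against -14.2 and -16.3, and its correlations with arrays of other groups were 0.913 to 0.929. The share of equal values in any pair of arrays was at most 0.248%, so no array was a copy of another. The median log2 fold change of all tested probe sets was -0.08 in unloaded against control, -0.05 in walked against unloaded and -0.11 in walked against control.

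The first comparison asked what 12 h of unloading changed. Rrad, a small GTP-binding protein that restrains calcium channels, fell from a signal of 1190.3 ± 147 (SD, n = 3) in control to 127 ± 18.1 (n = 3) in unloaded soleus, a log2 fold change of -3.23 ± 0.18. The inducible chaperone Hspa1a fell from 1003 ± 129 to 210.4 ± 45.7 (-2.27 ± 0.17). Hspa1a has a near-identical neighbouring copy, so this signal cannot be assigned to 1 of the 2 genes. The lysosomal protease Ctsl rose from 197 ± 39.4 to 999 ± 34.0 (2.36 ± 0.16), and the muscle ubiquitin ligase Trim63 from 657 ± 45.7 to 1285 ± 136 (0.97 ± 0.13; its other probe set had 0.46 and was not called). In all, 209 probe sets rose and 174 fell (383 called, limma), naming 134 genes higher and 109 lower. Of the 383, 184 changed at least 2-fold.

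The 10 largest rises were in Map3k12 (4.63 ± 0.28, from a mean of 10.2 to 257), the transferrin receptor Tfrc (3.04), the complex I subunit Ndufs1 (2.93), the proteasome subunit Psma2 (2.77), the small proteoglycan Dcn (2.70), the translation initiation helicase Eif4a2 (2.66), the fatty acid transporter Cd36 (2.61), the O-GlcNAc transferase Ogt (2.40), ceruloplasmin (Cp, 2.39) and Ctsl. All 4 probe sets of Dcn rose, by 1.27 to 2.70, and all 3 of Psma2, by 1.33 to 2.77. The 10 largest falls were in Rrad, Cth (-2.66), Acta2 (-2.42), Hspa1a, Enpep (-2.19), Klf6 (-2.12), Dlgap4 (-2.12), Nr4a1 (-2.10), the collagen chaperone Serpinh1 (-1.96) and the NADPH oxidase subunit Cyba (-1.94). Acta2, the smooth muscle actin, fell on 1 of 3 probe sets, and its brightest had a log2 fold change of -0.64. The folds of Map3k12, Tfrc, Ogt, Cth, Enpep and Dlgap4 are imprecise, since the dimmer group had mean signals of 8.13 to 11.3. The size of the Cd36 rise rests on control pool 3, with a signal of 47.1 against 382 and 418 in the other control pools, and was 1.58 without it. Cp, called on 2 of 3 probe sets with 0.59 on the other, was 1.62 without control pool 3, Ogt 1.79 without control pool 1, and Acta2 -1.59 without unloaded pool 2 and -3.15 without unloaded pool 1.

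Immediate early genes, which respond within minutes to hours to stimuli, were lower as a list (camera adjusted p = 0.00305; adjusted p = 0.493 with an estimated correlation). Of 27 measured, 7 fell and 1 rose; adjusted over the list alone, 8 fell and 2 rose. The falls included Klf6, Nr4a1, Dusp1 (-1.65), Id1 (-1.43) and Egr1 (-1.14), and Klf10 rose (1.24). Id1 fell on 1 of 2 probe sets (-0.38 on the other), and Egr1 on 2 of 4 (another had 0.10). Of 23 heat shock genes 4 fell, Hspa1a, Hspa5 (-0.97), Hspb1 (-0.87) and Hspb2 (-0.79); adjusted over the list alone, 6 fell and 2 rose. The list's adjusted p was 0.0401 (adjusted p = 0.388 with an estimated correlation). It was 0.190 with the mean of a gene's probe sets and 0.0664 with the pool number as a block, and lay between 0.0515 and 0.204 without control pool 1 or 3, unloaded pool 1, or walked pool 1 or 2. Hspb1 fell on 1 of its 4 probe sets, and another had 0.44. Of 12 angiogenesis genes 3 fell (4 adjusted over the list alone): the growth factor Fgf1 (-1.05) and the lipid phosphate phosphatases Plpp3 (-0.98) and Plpp1 (-0.89). That list's adjusted p was 0.00635 (adjusted p = 0.388 with an estimated correlation). Markers of smooth muscle, 5 genes, included 1 fall, Tagln (-0.96).

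Lipid metabolism genes were higher as a list (adjusted p = 0.00191; adjusted p = 0.413 with an estimated correlation). Of 34 measured, 5 rose and 0 fell, with the same counts adjusted over the list alone: Cd36, the uncoupling protein Ucp3 (1.08), Acsl6 (0.83), Decr1 (0.78) and the pyruvate dehydrogenase kinase Pdk4 (0.57 ± 0.15). The adipocyte marker Fabp4 also rose (1.52). Of 35 mitochondrial genes 6 rose and 0 fell (6 and 1 adjusted over the list alone), among them Ndufs1, Atp5pd (1.75), Ndufa5 (1.00) and Cox7b (0.80). That list's adjusted p was 0.00756 (adjusted p = 0.388 with an estimated correlation), 0.453 after quantile normalization and 0.0560 without unloaded pool 3. Of 14 translation factors 2 rose, Eif4a2 and the cap-binding protein Eif4e (1.46), and 4 adjusted over the list alone (adjusted p = 0.0197; adjusted p = 0.493 with an estimated correlation; 0.176 without control pool 1 and 0.0823 without unloaded pool 1). Of 40 ribosomal protein genes 8 rose and 0 fell (9 and 1 adjusted over the list alone), led by Rps3a (1.66) and Rpl35a (1.31), with a mean of 0.16 and a test upward but a median of -0.01. Their adjusted p was 0.0367 (adjusted p = 0.493 with an estimated correlation), 0.724 after quantile normalization, 0.0664 with the pool number as a block, and between 0.0802 and 0.136 without control pool 1 or 2 or unloaded pool 1 or 3. Among 11 fast contractile genes limma called 0 (5 higher at an unadjusted p under 0.05, 4 adjusted over the list alone), with a median of 0.35. That list's adjusted p was 0.0341 (adjusted p = 0.493 with an estimated correlation), 0.234 after quantile normalization, 0.0887 with the mean of a gene's probe sets, and between 0.0520 and 0.145 without control pool 1 or 3 or unloaded pool 3.

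No other list had a camera adjusted p under 0.05 in this comparison, which does not show that they were unchanged. Without unloaded pool 2, 9 lists passed, against 8 with all arrays. Of 28 proteasome and ubiquitin genes 5 rose (6, and 1 fell, adjusted over the list alone), including Psma2, Psme4 (1.87), Psma4 (1.75) and Trim63, with a list adjusted p of 0.0894. Growth arrest genes (11, adjusted p = 0.524) included 1 rise, the stress gene Gadd45a (1.27 ± 0.20; 2 rises and 1 fall adjusted over the list alone). Lysosome and calpain genes (18, 0.759) included 1 rise, Ctsl. Glucose metabolism genes (25, 0.759) held rises in Pfkfb1 (1.87; called on 2 of 4 probe sets, with -0.41 on another) and Slc16a1 (0.59) and falls in the glucose transporter Slc2a1 (-1.19) and Pgam1 (-0.94), with 3 falls adjusted over the list alone. Extracellular matrix genes (33, 0.433) held rises in Dcn and Lum (0.82) and falls in Serpinh1, Spp1 (-1.15) and P4ha1 (-0.99). Inflammatory mediators (22, 0.759) held rises in Il15 (1.59; called on 1 of 3 probe sets, with 0.47 on another) and Il6r (1.26) and 1 fall, Nfkb1 (-0.68). Myogenic growth genes (21, 0.759) held 3 falls, Ankrd1 (-1.40), Myf6 (-0.61) and Igfbp6 (-0.54). Single falls were in slow contractile genes (9, 0.398; Tpm3, -0.95, on 1 of 4 probe sets, with -0.14 on another; 3 rises and 2 falls adjusted over the list alone), clock genes (9, 0.759; Bmal1, -1.03; 1 rise and 1 fall), energy signalling (18, 0.759; Srebf1, -1.19; 2 and 2), polyamine and amino acid genes (17, 0.347; Odc1, -0.85; 2 falls) and smooth muscle markers (5, 0.388; 2 falls). Glucocorticoid targets (8, 0.581) held rises in Klf9 (0.90) and Errfi1 (0.88), and leukocyte markers (11, 0.919) 1 rise, Cd48 (1.40). Adipocyte markers (5) had an adjusted p of 0.521. Limma called 0 genes of the synapse list (10, 0.893), red cell (4, 0.893) and endothelial (7, 0.581) markers, with 0 at an unadjusted p under 0.05, and 0 Schwann cell and nerve markers (7, 0.919), with 2 higher and 1 lower unadjusted. The 3 mast cell markers were too few to test. In the lysosome, clock, glucocorticoid, leukocyte, red cell and adipocyte lists the test pointed up while the median was below 0.

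Of the 20 genes fixed in advance, 8 were called: Ctsl, Gadd45a, Ucp3, Trim63, Pdk4, Plpp1, Egr1 and Hspa1a. Not called were Cdkn1a (0.47), Lpl (0.46 ± 0.16, adjusted p = 0.111), Myh7 (0.24), Hmox1 (0.06), Slc2a4 (0.00), Col3a1 (-0.03), Col1a1 (-0.19), Nr4a3 (-0.33), Hk2 (-0.36), Vegfa (-0.50 ± 0.18, adjusted p = 0.122), Myc (-0.69) and Fos (-0.77, adjusted p = 0.120). Vegfa fell on its 3 other probe sets, and Fos on 1 of 3. The count of 383 was 245 without unloaded pool 1 and 230 without unloaded pool 2, 228 with no filter and 243 without a trend, while 46 of 67 called probe sets of named genes kept their call in every fit that left out 1 array. Among the largest changes and fixed genes, calls were lost for Pdk4 without any 1 array but control pool 2 (adjusted p up to 0.116), Cd36 without any 1 unloaded or walked pool (0.0936), Cp without any 1 unloaded pool (0.0903), Ogt without unloaded pool 1 or 2 (0.0808), Acta2 without any 1 control pool or unloaded pool 3 (0.0708), Cyba without control pool 1 or 3 or unloaded pool 1 (0.0706), Enpep without control pool 1 or 2 (0.0663) and Dlgap4 without control pool 2 (0.0605).

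**Figure D1:**
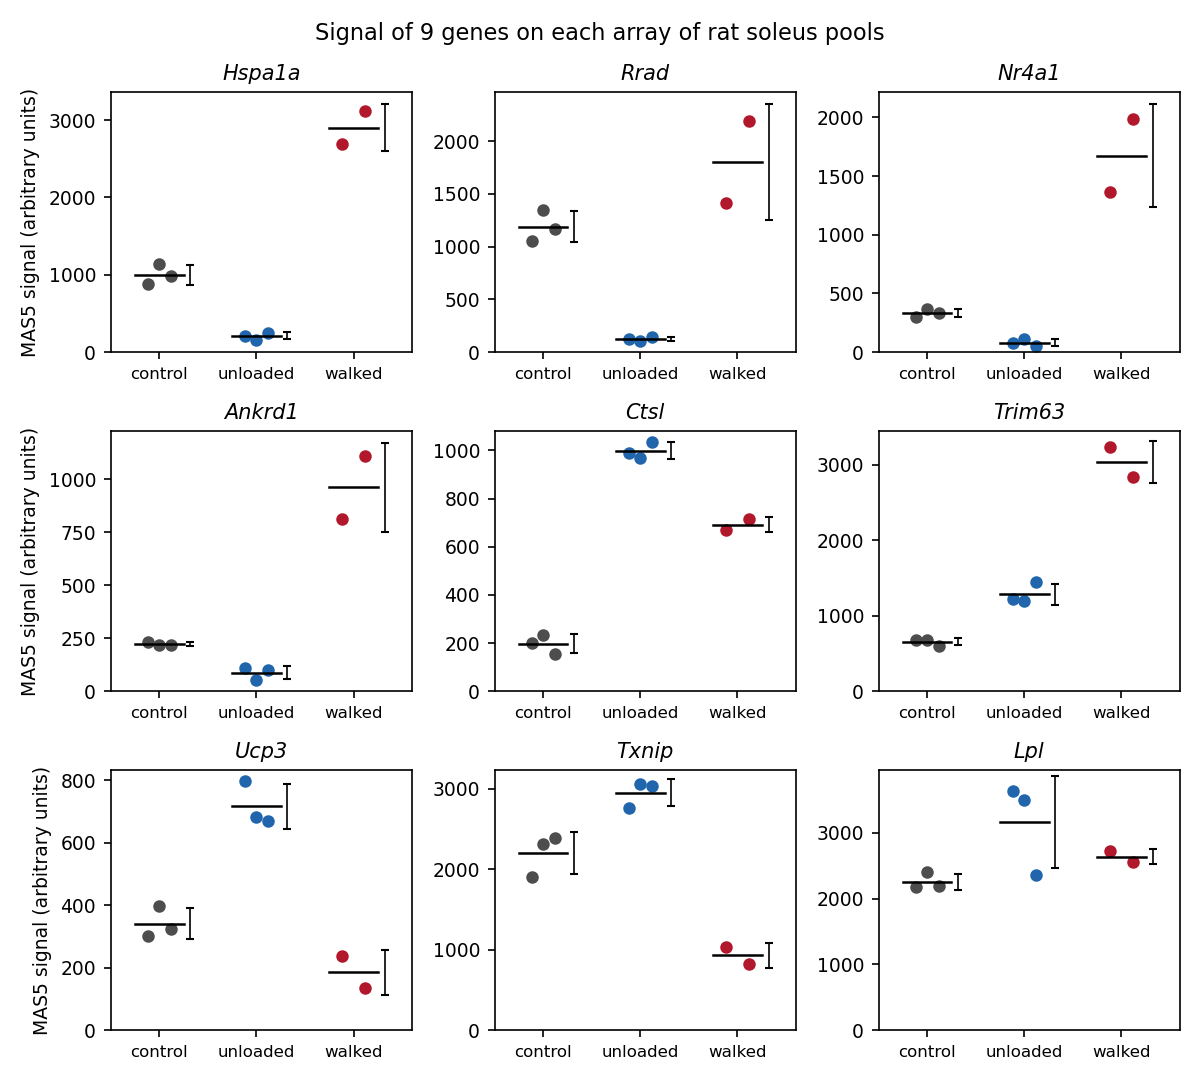
MAS5 signal (arbitrary units, linear axis from 0) of 9 genes in control, unloaded and walked soleus, where each point is 1 array of a pool, the line is the group mean and the bar is the SD. Hspa1a fell from a mean of 1003 to 210.4 and reached 2904 after walking, Ctsl rose from 197 to 999, and Trim63 went from 657 to 1285 and 3034.

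The second comparison asked what intermittent walking changed in muscle that had just been unloaded. Hspa1a rose from 210.4 ± 45.7 (n = 3) to 2904 ± 307 (SD, n = 2), a log2 fold change of 3.81 ± 0.19. Rrad rose from 127 to 1805 (3.81 ± 0.20), and the orphan nuclear receptor Nr4a1 from 80.8 ± 27.9 to 1673 ± 439 (4.41 ± 0.27). Trim63 rose again, to 3034 ± 278 (1.24 ± 0.14), on 1 of 2 probe sets; the other had 0.97 and was not called. G0s2, an inhibitor of the lipase that breaks down stored triglyceride, fell from 333 ± 48.2 to 21.8 ± 13.2 (-4.07 ± 0.35), and Ucp3 fell from 716 to 173 (-2.04 ± 0.17). In all 143 probe sets rose and 77 fell (220 called, limma), naming 80 genes higher and 65 lower, and 146 of the 220 changed at least 2-fold.

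The 10 largest rises were in Nr4a3 (7.35), Nr4a1, the stress transcription factor Atf3 (4.12), the cAMP-responsive regulator Crem (3.85), Rrad, Hspa1a, the insulin receptor substrate Irs2 (3.64), the muscle ankyrin repeat protein Ankrd1 (3.50), the growth factor Hbegf (3.26) and hexokinase Hk2 (3.17). The 7.35 of Nr4a3 comes from a probe set with 2 of 3 unloaded arrays at the floor, and the gene's brighter probe set had 2.04 ± 0.43. Crem had 1.86 on its brightest probe set and Hk2 1.19. The 10 largest falls were in G0s2, Scarb1 (-2.69), Cyp4b1 (-2.33), Gucy1a1 (-2.21), Ocln (-2.21), Ucp3, Tle1 (-2.03), Txnip (-1.98), an inhibitor of thioredoxin and glucose uptake, Klf10 (-1.97) and Tnfsf13 (-1.95). Irs2 rose on 1 of 3 probe sets, from a dim unloaded mean of 7.27, and another had 0.58. Tnfsf13 and Scarb1 fell on 1 of 3 probe sets, with 0.37 and -0.50 on another. The folds of Scarb1, Ocln and Tnfsf13 are imprecise too, with walked means of 5.06, 10.5 and 12.1. G0s2 was -4.73 without walked pool 1 and -3.41 without walked pool 2, and Gucy1a1 -1.26 and -3.17.

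Heat shock genes rose as a list (adjusted p = 2.66e-09; adjusted p = 0.0272 with an estimated correlation), and 21 of 23 lay above 0. Of the 23, 6 rose and 0 fell (9 and 0 adjusted over the list alone), including Hspa1a, Hmox1 (1.88), the endoplasmic reticulum chaperone Hspa5 (1.75) and Hspb1 (1.37, on 1 of 4 probe sets, with 0.08 on another). Immediate early genes rose as a list too (adjusted p = 2.66e-09; adjusted p = 0.315 with an estimated correlation), with 11 of 27 up and 1 down, or 12 and 3 adjusted over the list alone. Examples were Nr4a1, Atf3, Dusp1 (2.39), Id1 (1.99, on 1 of 2 probe sets, with 0.20 on the other), Egr1 (1.95, on 2 of 4, with 0.15 on another) and Fos (1.70), and the fall was in Klf10. Lipid metabolism genes fell as a list (adjusted p = 0.00144; adjusted p = 0.427 with an estimated correlation), with 4 of 34 down and 0 up, or 9 and 0 adjusted over the list alone: Ucp3, the carnitine palmitoyltransferases Cpt1a (-1.08) and Cpt2 (-0.56), and Etfa (-0.64). Without 1 array, Cpt1a lost its call without unloaded pool 1 or walked pool 1 (adjusted p up to 0.185), Cpt2 without control pool 2 or any unloaded or walked pool (0.258), and Etfa without control pool 1 or 2, unloaded pool 1 or 3 or either walked pool (0.244).

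No other list had a camera adjusted p under 0.05 here, which does not show that they were unchanged. Without unloaded pool 2, 6 lists passed, against 3 with all arrays. Glucose metabolism genes (25, adjusted p = 0.4996) held rises in Slc2a1 (2.30), Pgam1 (1.46) and Hk2 (1.19) and a fall in Pfkfb1 (-1.94; called on 1 of 4 probe sets, with 0.19 on another). Myogenic growth genes (21, 0.718) held rises in Ankrd1, Myf6 (1.23) and Csrp3 (0.87) and a fall in Igfbp5 (-1.91; -0.31 on its other probe set). Extracellular matrix genes (33, 0.718) held rises in Serpinh1 (1.81) and P4ha1 (1.27; 3 rises and 1 fall adjusted over the list alone). Angiogenesis genes (12, 0.124) held a rise in Vegfa (1.80 ± 0.20, with all 4 probe sets up by 1.62 to 1.81) and a fall in Nrp1 (-0.94; 3 and 1 adjusted over the list alone). Growth arrest genes (11, 0.195) held rises in Ddit3 (1.26) and Mdm2 (0.96) and a fall in Txnip (3 and 2), inflammatory mediators (22, 0.124) a rise in the chemokine Ccl2 (1.89; 4 and 1), glucocorticoid targets (8, 0.361) a rise in Sgk1 (1.25; 2 and 1), and polyamine and amino acid genes (17, 0.166) a rise in Slc3a2 (1.196; 2 and 2). Clock genes (9, 0.885) held a rise in Bmal1 (1.30) and a fall in Dbp (-1.14). Fast contractile genes (11, 0.124) held falls in the troponin Tnni2 (-0.83) and the myosin Myh2 (-0.64). Single calls were rises of Trim63 among proteasome and ubiquitin genes (28, 0.885), Slc25a5 (1.203) among mitochondrial genes (35, 0.361) and Runx1 (0.87) in the synapse list (10, 0.552). Single falls were Eef2k (-1.004; -0.28 on its other probe set) among translation factors (14, 0.124), Prkab1 (-0.64) in energy signalling (18, 0.885), Rps27l (-0.55) among ribosomal proteins (40, 0.440; 0 adjusted over the list alone), RT1-Da (-0.85; -0.21 on its other probe set) among leukocyte markers (11, 0.4996) and Prx (-1.23) among Schwann cell and nerve markers (7, 0.4996; 2 adjusted over the list alone). Limma called 0 lysosome and calpain genes (18, 0.4996; 4 lower unadjusted), slow contractile genes (9, 0.0858; 2 higher unadjusted), adipocyte markers (5, 0.885; 1 lower unadjusted and adjusted over the list alone), smooth muscle markers (5, 0.124; 2 higher unadjusted and adjusted over the list alone) and mast cell markers (3, not tested; 0 unadjusted), and 0 red cell (4, 0.567) and endothelial markers (7, 0.4996; 0 unadjusted in both). In the matrix, clock, myogenic and energy lists the median and the mean differed in sign.

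Among the 20 fixed genes, those not called were Cdkn1a (0.90, adjusted p = 0.0965), Myc (0.63), Plpp1 (0.50 ± 0.14, adjusted p = 0.0711), Myh7 (0.24), Slc2a4 (0.03), Col3a1 (-0.09), Lpl (-0.24), Col1a1 (-0.34), Ctsl (-0.53 ± 0.17, adjusted p = 0.131), Pdk4 (-0.56, adjusted p = 0.0915) and Gadd45a (-0.70, adjusted p = 0.121). These values are from the brightest probe set, and Col1a1 fell on 1 of its 3 others (-0.94). The count of 220 was 122 without walked pool 1 and 120 without walked pool 2, when the lone walked array was assumed to vary like the other groups. Calls were lost for Fos (adjusted p up to 0.0940) and Irs2 (0.131) without walked pool 1 or 2, Nr4a3 on its brighter probe set without unloaded pool 2 or either walked pool (0.191), Hk2 on its brighter probe set without unloaded pool 3 or walked pool 2 (0.170), Hbegf without walked pool 2 (0.0627), Ocln without unloaded pool 2 or walked pool 1 (0.0726), Tnfsf13 without unloaded pool 2 or 3 or either walked pool (0.0972), Scarb1 without any 1 array but control pool 3 and unloaded pool 2 (0.120) and Gucy1a1 without any 1 array but control pool 3 and walked pool 2 (0.275), while 31 of 61 called probe sets of named genes kept their call in every such fit.

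The third comparison asked how muscle that had been unloaded and then walked differed from that of caged rats. Trim63 was higher at 3034 against 657 (2.21 ± 0.14), and Ctsl at 692 ± 31.1 against 197 ± 39.4 (1.83 ± 0.17). Hspa1a, lower in unloaded muscle, was higher here (1.54 ± 0.19), while Txnip (-1.25 ± 0.15), G0s2 (-3.04) and Ucp3 (-0.93) were lower. In all 234 probe sets were higher and 242 lower (476 called, limma), naming 144 genes higher and 186 lower, and 213 differed at least 2-fold.

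The 10 largest rises were in Nr4a3 (6.30, the dim probe set), Tfrc (3.85), Map3k12 (3.60), Eif4a2 (3.02), Ndufs1 (2.96), the nucleolar protein Gnl3 (2.79), Hbegf (2.73), Atf3 (2.67), Irs2 (2.66) and heme oxygenase Hmox1 (2.65). The 10 largest falls were in Plpp3 (-3.49 on a dim probe set and -1.25 on the brighter one), G0s2, Scarb1 (-2.82), the phosphatase Dusp6 (-2.30), Gpr161 (-2.29), Sncg (-2.17), Tnfsf13 (-2.14), Kiaa0930 (-2.01), Papss2 (-1.97) and Cyba (-1.78). Another probe set of Tnfsf13 had 1.40 and was not called, and Irs2 rose on 1 of 3 probe sets. The least changed probe set had 0.92 for Gnl3, 0.11 for Scarb1, -0.60 for Dusp6 and -0.20 for Kiaa0930. The folds of Tfrc, Map3k12, Irs2, Plpp3, Scarb1, Dusp6, Gpr161, Tnfsf13 and Papss2 are imprecise, with means of 5.06 to 14.4 in the dimmer group. G0s2 was -3.71 without walked pool 1 and -2.38 without walked pool 2, Gpr161 -1.42 and -3.15, Ucp3 -1.34 and -0.52, and Nr4a3 5.63 without control pool 3.

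Heat shock genes were higher as a list (adjusted p = 0.000201; adjusted p = 0.133 with an estimated correlation), with 6 of 23 up and 0 down, or 10 and 1 adjusted over the list alone, including Hmox1 (1.94), Hspa1a, Hsph1 (0.73) and Hspe1 (0.57). Immediate early genes were higher too (adjusted p = 0.000201; adjusted p = 0.432 with an estimated correlation), with 6 of 27 up and 0 down, or 9 and 2 adjusted over the list alone, including Atf3, Nr4a1 (2.30) and Klf4 (2.02). Mitochondrial genes were higher (adjusted p = 0.000446; adjusted p = 0.189 with an estimated correlation), with 8 of 35 up and 0 down, the same counts adjusted over the list alone, including Ndufs1, Atp5pd (1.70) and Ndufa5 (1.07). Slow contractile genes were higher (adjusted p = 0.0202; adjusted p = 0.320 with an estimated correlation), with 3 of 9 up and 0 down, or 5 and 1 adjusted over the list alone: Myl2 (0.60), Tnni1 (0.58) and Myl3 (0.58). Myl2 lost its call without control pool 1 or 2 or either walked pool (adjusted p up to 0.184), Tnni1 without any 1 control or walked pool (0.217), and Myl3 without those or unloaded pool 3 (0.219). After quantile normalization the adjusted p of mitochondrial genes was 0.587 and that of slow contractile genes 0.508, and the latter was 0.0966 with no filter, 0.0560 with the mean of a gene's probe sets, 0.0642 without control pool 1 and 0.0526 without walked pool 2.

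No other list had a camera adjusted p under 0.05 against control, which does not show that they were equal. Without unloaded pool 2, 5 lists passed, against 4 with all arrays. Proteasome and ubiquitin genes (28, adjusted p = 0.219) held 5 rises, including Trim63, Psma4 (1.66) and Psme4 (1.41; 6 and 1 adjusted over the list alone). Lysosome and calpain genes (18, 0.934) held a rise in Ctsl and a fall in Ctsh (-0.71). Glucose metabolism genes (25, 0.209) held rises in Slc2a1 (1.11), Hk2 (0.83) and Pgam1 (0.52; 3 and 1 adjusted over the list alone), and translation factors (14, 0.813) rises in Eif4a2 and Eif4e (1.41; 2 and 2). Growth arrest genes (11, 0.0686) held rises in Trib3 (1.53) and the cell cycle inhibitor Cdkn1a (1.37) and a fall in Txnip (4 and 2). Ribosomal protein genes (40, 0.392) held 5 rises, led by Rps3a (1.87), and 2 falls, Rpl14 (-0.69) and Rpl13a (-0.51; 7 and 8 adjusted over the list alone). Extracellular matrix genes (33, 0.775) held a rise in Dcn (1.51; called on 2 of 4 probe sets, with 0.27 to 2.45 over the 4) and falls in Col1a2 (-1.03), Pcolce (-0.84) and Timp2 (-0.72; 2 and 3). Angiogenesis genes (12, 0.718) held a rise in Vegfa (1.31) and falls in Nrp1 (-1.45) and Plpp3 (1 and 3). Lipid metabolism genes (34, 0.813) held falls in Vldlr (-0.98), Ucp3 and Cpt1a (-0.91). Myogenic growth genes (21, 0.813) held a rise in Ankrd1 (2.10) and falls in Igfbp5 (-1.42, on 1 of 2 probe sets with 0.45 on the other, and -0.94 without walked pool 1) and Igfbp6 (-0.84; 4 and 2). Glucocorticoid targets (8, 0.147) held rises in Errfi1 (1.79) and Sgk1 (0.94), inflammatory mediators (22, 0.209) rises in Ccl2 (1.16, on 1 of 2 probe sets) and Il6r (0.95), and the synapse list (10, 0.718) a rise in Runx1 (0.69) and a fall in Agrn (-0.82; 1 and 2). The Ccl2 call held in 2 of 8 fits that left out 1 array, and the value was 0.62 without walked pool 2 (adjusted p = 0.368). Polyamine and amino acid genes (17, 0.775) held falls in Bcat2 (-1.10) and Bckdhb (-0.70; 1 and 2), and leukocyte markers (11, 0.718) falls in Cd74 (-0.65) and RT1-Da (-0.58, with -0.24 on its other probe set; 1 and 2). Single falls were Dbp (-1.33) among clock genes (9, 0.718; 1 and 1), Casq1 (-0.48) among fast contractile genes (11, 0.855), Prkag1 (-0.86; -0.48 without walked pool 2) in energy signalling (18, 0.718; 1 and 2) and Cnp (-1.32) among Schwann cell and nerve markers (7, 0.718). Limma called 0 red cell (4, 0.775), adipocyte (5, 0.540; 1 and 1 adjusted over the list alone) and smooth muscle (5, 0.718) markers, with 1 higher and 1 lower unadjusted in each, and 0 endothelial (7, 0.985) and mast cell (3, not tested) markers, with 0 unadjusted. The median and the test differed in sign for the proteasome, inflammatory, myogenic, polyamine, translation, ribosomal, endothelial and smooth muscle lists, and the mean and the test for fast contractile genes.

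Among the 20 fixed genes, those called were Trim63, Ctsl, Hmox1, Hspa1a, Nr4a3 (1.71 on the brighter probe set), Cdkn1a, Vegfa, Hk2, Egr1 (0.81; 0.25 on another probe set) and Ucp3. Not called were Fos (0.93, adjusted p = 0.0804), Gadd45a (0.58, adjusted p = 0.130), Myh7 (0.47, adjusted p = 0.0618), Lpl (0.23), Slc2a4 (0.03), Pdk4 (0.01), Myc (-0.06), Col3a1 (-0.12), Plpp1 (-0.39, adjusted p = 0.0944) and Col1a1 (-0.53, adjusted p = 0.173). Of these, other probe sets were called lower for Plpp1 (-0.60 and -0.73) and Col1a1 (2 of 3 others, -1.22 and -1.33), and higher for Myh7 (1.06). The count of 476 was 258 without control pool 2, 297 without control pool 3, 145 without walked pool 1, 104 without walked pool 2, 216 with no filter and 211 without a trend. The near balance of directions did not hold in these: 168 higher and 90 lower, 199 and 98, 94 and 51, 66 and 38, 124 and 92, and 129 and 82, and 167 and 84 of 251 with the pool number as a block. Calls were lost for Hk2 without any 1 array (adjusted p up to 0.331), Ucp3 without control pool 2 or walked pool 2 (0.251), Cdkn1a (0.0874), Irs2 (0.222), Hbegf (0.103), Dusp6 (0.0755), Tnfsf13 (0.0601) and Kiaa0930 (0.110) without either walked pool, Egr1 (0.191) and Nr4a3 on its brighter probe set (0.215) without control pool 1 or 3 or either walked pool, Scarb1 without control pool 3 or either walked pool (0.0786), Sncg without control pool 2 or 3, unloaded pool 1 or either walked pool (0.208), Gpr161 without any 1 control pool or walked pool 1 (0.131), and Papss2 (0.163) and Cyba (0.205) without any 1 control or walked pool, while 28 of 79 called probe sets of named genes kept their call in every such fit.

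**Figure D2:**
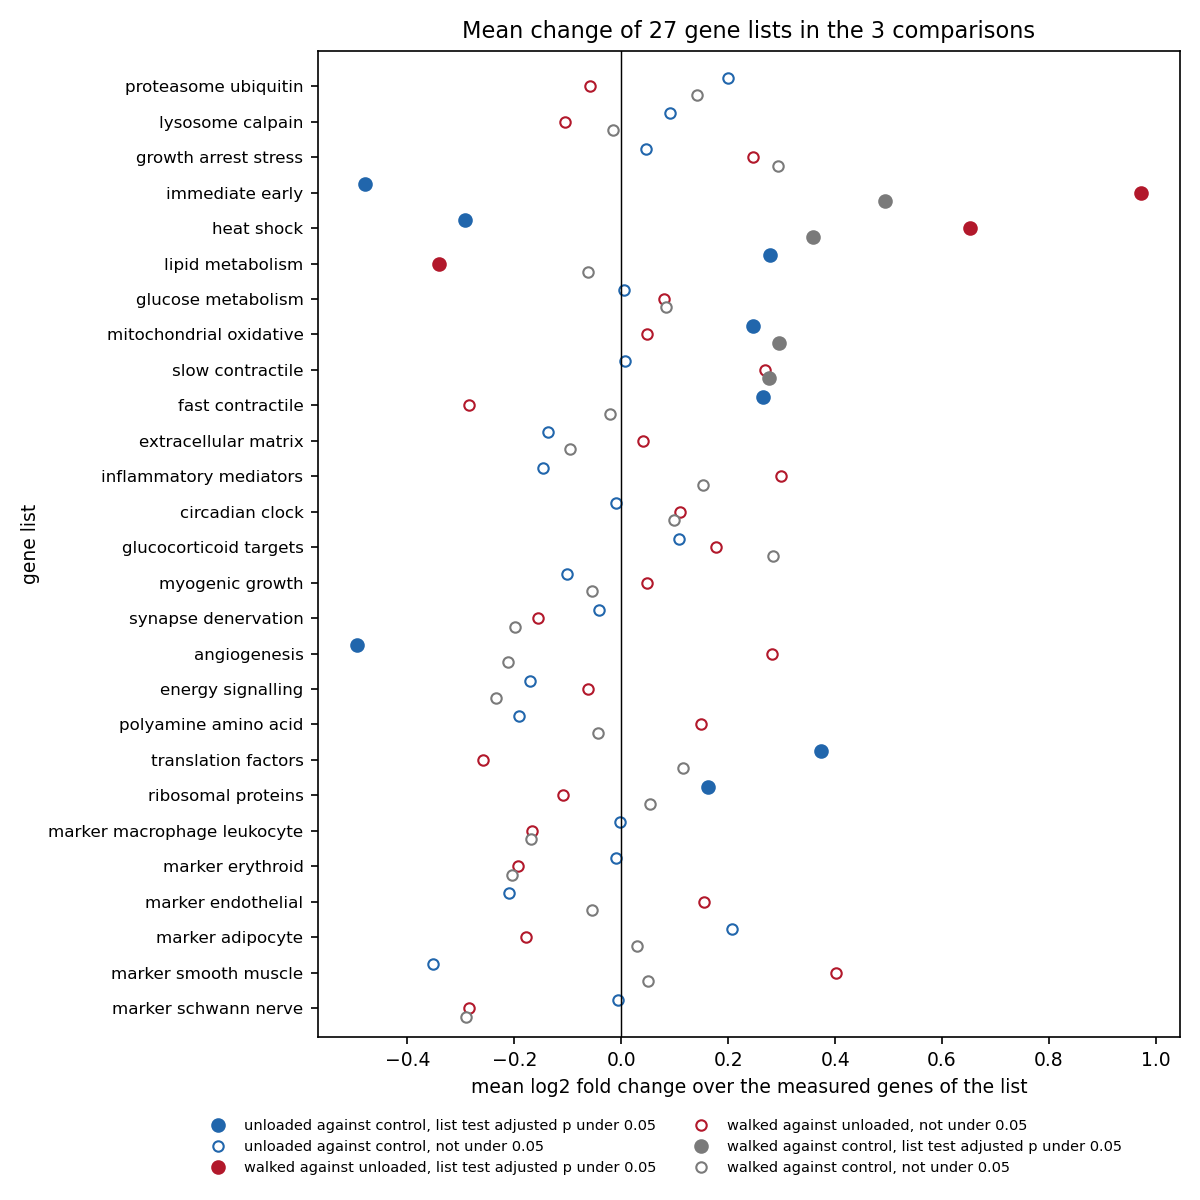
Mean log2 fold change over the measured genes of 27 gene lists in the 3 comparisons, where filled points mark lists with a camera adjusted p under 0.05. Heat shock and immediate early genes lie below 0 in unloaded against control and above 0 in both comparisons of walked muscle.

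The order of the treatments raised the question whether walking turned the changes of unloading around. At 1 probe set per gene, 196 genes were called in unloaded against control, 117 higher and 79 lower. Of these, 159 (81.1%) had the opposite sign in walked against unloaded. The shared unloaded arrays alone raise this share: among the 196 genes with the smallest p, simulations gave a median of 62.8% (55.1 to 71.9%) with walked equal to unloaded and 85.7% (76.5 to 92.3%) with no group differing. The observed share lay above the range with walked equal to unloaded and inside that with no group differing. Runs with walked equal to unloaded called 382 to 497 genes in unloaded against control, and runs with no group differing at most 1. Neither matched the 196 called here, so the share by itself decides nothing. The unloaded arrays were therefore divided 1 and 2, with different arrays in each step. Of the 100 genes with the smallest p in the first step, 65 to 80% then had the opposite sign over the 6 divisions, against 49.0 to 52.3% from the shares of higher and lower genes. The first step called 26 to 141 genes in these divisions, so the 100 were not all called in each. The lowest share, 65%, came from the division with 141 called. With all arrays, both steps called 44 genes, of which 32 fell and then rose, 11 rose and then fell, and 1, Trim63, rose in both. Among the 32 were Rrad, Hspa1a, Nr4a1, Atf3, Ankrd1, Dusp1, Serpinh1 and Slc2a1; among the 11 were Ucp3, Klf10, Tle1 and Cyp4b1. The 43 with opposite signs were 27 without walked pool 1 and 28 without walked pool 2.

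Other genes differed from control in both treated groups. Of the 196, 74 differed between walked and control in the direction of unloading, 56 higher and 18 lower, while 14 differed in the other direction and 108 were not called. The 56 included Map3k12, Tfrc, Ndufs1, Eif4a2, Ctsl, Psma4 and, on 2 of 4 probe sets, Dcn, and the 18 included Cyba, Plpp3 and Igfbp6. With the control arrays divided in the same way, 68 to 76% of the 100 genes had the same sign in both comparisons. The shares of higher and lower genes alone would give 41.2 to 47.0%. The first comparison called 59 to 163 genes in these divisions, so the 100 were not all called in each. This division removes only the noise of single control arrays. An error common to all control arrays would also give the same sign in both comparisons. Such an error cannot be told apart here from an effect of unloading that walking left in place. Across genes, which are not independent replicates, the log2 fold changes of the 2 steps correlated at -0.43 (-0.45 simulated with no group differing), with a covariance of -0.107 against -0.0382 simulated, a difference of -0.0685. Those of unloaded and walked against control correlated at 0.48 (0.44 simulated), with a covariance of 0.122 against 0.0377, a difference of 0.0847.

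**Figure D3:**
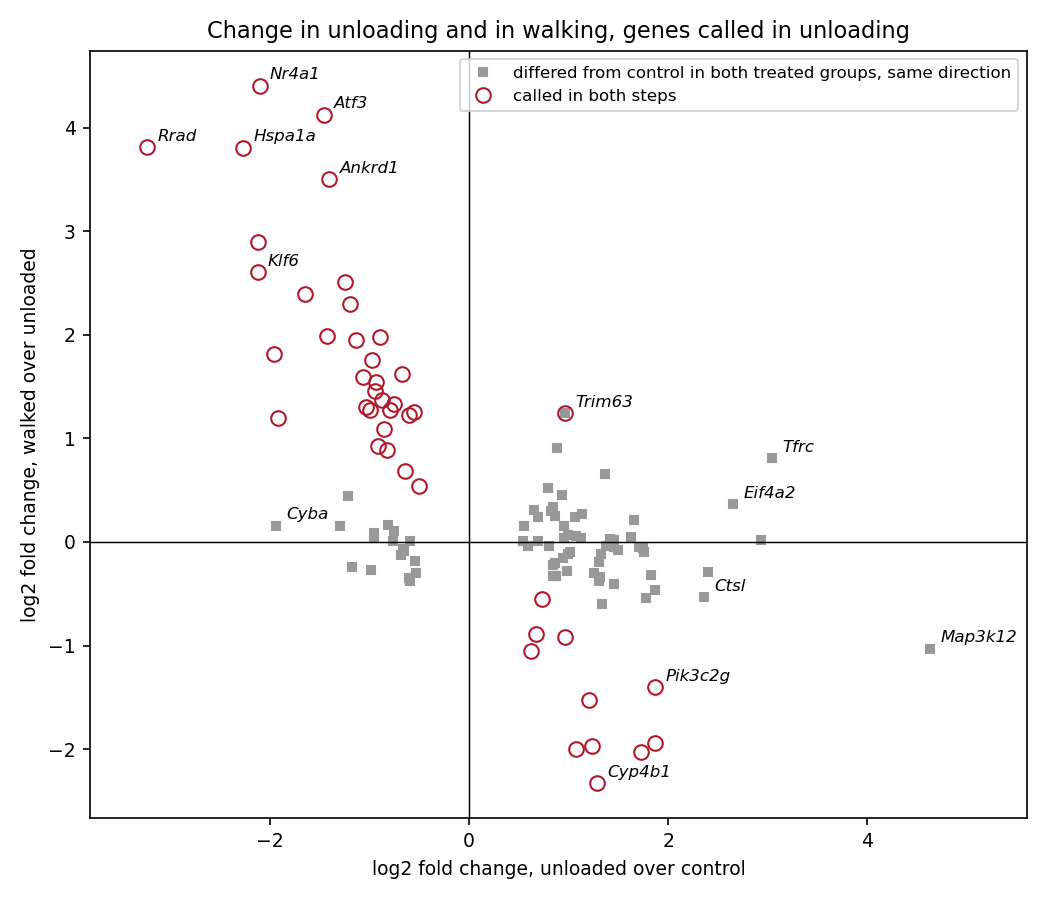
Log2 fold change of unloaded over control (x axis) against walked over unloaded (y axis) for genes called in unloaded against control, with red circles for the 44 genes called in both steps and grey squares for the 74 that differed from control in both treated groups in one direction. The circles lie in the upper left and lower right, except Trim63, while most squares lie near 0 on the y axis.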

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

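No test was run in this part, and the rule that found these signals was written after the data had been seen. Of 3496 probe sets left out because their mean signal over all arrays was low, those of 5 named genes still had, on every array of a treated group, a signal above the filter and at least 2-fold that of every control array. In walked muscle these were Pde4d (mean signal 34.3, against 2.93 in control), Cd24 (26.7 against 5.13) and Myc (29.8 against 5.13). In unloaded muscle they were Rpa3 (42.1 against 10.9) and Cyp1b1 (27.1 against 10.2). With unnamed probe sets included, 4 were higher in walked than control muscle by this rule and 4 lower, and 3 were higher in unloaded muscle and 1 lower, so the number in the walked group is matched by its mirror image. The Myc probe set that was tested had a log2 fold change of -0.06 in walked against control and was not called, while that of Pde4d was called higher in walked (1.34) and unloaded muscle (1.38) against control. The Cyp1b1 probe set that was tested had -0.36 in unloaded against control and was not called. Groups of 2 or 3 arrays are too small for a test of single outlying arrays.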

How the results depend on the processing

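The fit on probe sets with a plain name ending was chosen after seeing the data, and the other alternatives before. Over 4189 values of named genes under these alternatives, 3578 kept their direction and side of the threshold, 572 lost their call, 13 gained one and 26 changed sign, 0 of these among called values. Of 195 values of called lists, 153 kept their call and 42 lost it. Counts in unloaded against control, then walked against control, were 228 and 216 with no filter, which tests more probe sets, and 243 and 211 without a trend, where the cause was not tested. Plain-ending probe sets gave 230 in unloaded against control and 124 in walked against unloaded, from fewer probe sets tested. The pool number as a block gave 394, 177 and 251 (walked against control). Deviations of arrays with one number correlated at -0.07 to 0.05, so no pairing of the pools was seen. With so few arrays this cannot exclude a shared day or batch, which the labels do not state. Shifted lists numbered 5 in unloaded against control and 2 in walked against control after quantile normalization. They numbered 5 in walked against unloaded with the mean of a gene's probe sets. The cause was not tested. With an estimated correlation they numbered 0, 1 and 0 in the 3 comparisons. A higher correlation does not account for all of this loss. For heat shock genes the estimate, 0.00296, was below the preset 0.01. Their camera p still went from 0.0119 to 0.0431 in unloaded against control and from 1.65e-10 to 0.00101 in walked against unloaded.

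Leaving out 1 array gave 230 to 405 called probe sets in unloaded against control (lowest without unloaded pool 2), 120 to 261 in walked against unloaded and 104 to 504 in walked against control (lowest without walked pool 2 in both). It gave 4 to 9, 3 to 6 and 3 to 5 shifted lists, 27 to 47 genes called in both steps with opposite sign, and 79.4 to 83.7% opposite signs. A lone walked array was assumed to vary like the other groups. The cause of these differences was not tested.

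Signs changed in genes near 0 and not called. Quantile normalization gave Slc2a4 -0.0679, -0.00452 and -0.0724 in the 3 comparisons, and in walked against control Pdk4 -0.10 and Myc 0.0423. The block gave Slc2a4 -0.0122 in walked against unloaded and -0.0103 in walked against control, and Pdk4 -0.0208. Leaving out 1 array gave, in unloaded against control, Hmox1 -0.11 to 0.26, Slc2a4 -0.0751 to 0.0805, Col3a1 -0.16 to 0.12, Col1a1 -0.40 to 0.0223 and Nr4a3 -0.69 to 0.0766. In walked against unloaded it gave Slc2a4 -0.0495 to 0.11 and Col3a1 -0.19 to 0.0336. In walked against control it gave Slc2a4 -0.0108 to 0.0767, Pdk4 -0.11 to 0.17, Myc -0.31 to 0.14 and Col3a1 -0.25 to 0.0323. Their cause was not tested. Signals near the floor of 4.10 limit the folds of dim genes: Scarb1 lost its call with the higher floor.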

Other observations

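The tests of divided arrays, ribosomal protein spread, clock genes and leukocyte markers below were chosen after the result was seen. Genes that differed from control in both treated groups are given here as single values, chosen after they were seen, with no test of a group; all but Cyba lie outside the naming rule. In unloaded and then walked muscle against control, the respiratory chain subunits Ndufb3 (1.12 and 1.16), Ndufb1 (1.07 and 1.13) and Ndufa4 (0.96 and 1.11) were higher, while the assembly factors Uqcc2 (-0.65 and -0.74) and Coa3 (-0.77 and -0.76) were lower. Prdx1 had 1.70 and 1.66, Idh1 1.78 and 1.24, and the iron regulatory protein Ireb2 1.45 and 1.47, while the NADPH oxidase subunit Cyba (-1.94 and -1.78) was lower. Of cytoskeletal genes, Pls3 (1.37 and 2.02) and Cdc42 (1.42 and 1.45) were higher, and Myl9 (-1.18 and -1.42), Tuba4a (-1.21 and -0.77) and Tubb5 (-0.81 and -0.65) lower. Genes that fell with unloading and rose with walking included Ppp1r15a (-1.24 and then 2.51), Dnajb5 (-0.89 and 1.98) and the prolyl hydroxylase Egln3 (-0.55 and 1.25).

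The first pattern is the set of differences between unloaded and control muscle. Of the 10 splits of the 6 arrays, 1, the real one, called as many as 383 probe sets, and the highest other called 0; 10 splits are too few for a share under 0.05. If single probe sets had hybridised differently on the control arrays, the other probe sets of a gene should keep under 25% of its change. Only 32 of 71 genes with rises of at least 2-fold and 24 of 42 with such falls had another tested probe set. These kept 47.5% of the rises (95% bootstrap interval 42.8 to 62.4, 30 of 32 genes with the same sign). They kept 59.7% of the falls (39.5 to 81.8, 22 of 24). Those from another accession kept 45.2% (28.9 to 67.9) and 53.6% (26.2 to 89.1). For the genes with another probe set this argues against the explanation by a narrow margin. The rises missed the 50% set beforehand for a clear exclusion. Genes with 1 probe set, among them Map3k12, Tfrc, Ndufs1 and Ogt, were not tested. In walked against unloaded, where no control array enters, falls kept 34.5% (17.2 to 76.5). For falls, a share near the bound therefore need not come from the control arrays. Rises in walked against unloaded kept 62.8% (53.6 to 82.7), or 65.1% from another accession (49.7 to 85.1). These shares are above those of the rises in unloaded against control, with overlapping intervals, so the same cannot be said for rises. In walked against control, falls kept 28.8% (16.6 to 43.6), or 25.6% from another accession (1.74 to 43.7), so the explanation stays open for them. Ribosomal protein genes changed unequally: their SD of log2 fold changes was at least 2.15 times as high against control (0.49 in both comparisons) as between walked and unloaded muscle (0.23), which handling the control arrays apart would give, and so would an effect of unloading that walking left in place, so the explanations cannot be told apart.

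The second pattern is the opposite change after walking. Noise of single unloaded arrays, shared by both steps, would give opposite signs. With different unloaded arrays in each step, at least 65% of 100 genes, not all of them called, still had opposite signs. This argues against that noise as the whole cause. The 43 genes called in both steps with opposite sign, against at most 1 in simulations with walked equal to unloaded, decide nothing, since walked and unloaded cannot differ there by construction. An error common to all 3 unloaded arrays cannot be told apart from unloading, and the walked rats also differed in treadmill exposure and time since the start, which no array separates. That reloading itself turned these genes stays a hypothesis, which rats returned to the cage after unloading, without the treadmill and sampled at the same time, would test.

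The third pattern is the higher heat shock and immediate early genes in walked muscle. Blood or leukocytes entering the muscle would raise their markers. The median log2 fold change was -0.0513 for 11 leukocyte markers and -0.32 for 4 red cell markers. This argues against an entry large enough to raise these markers as a set. Of 19 listed leukocyte genes on the array only 11 were measured. Entry of few cells, or of cells without these markers, was not excluded. A later time of day stays open. The median absolute change of 9 clock genes was 0.51, with Bmal1 up (1.30) and Dbp down (-1.14). That is short of the change of 1 set for that explanation but above the 0.25 that would exclude it. Bmal1 had fallen in unloaded against control (-1.03), and its 0.27 in walked against control was not called. Dbp was lower in walked than in control muscle too (-1.33). The labels give no clock time of sampling, so whether the walked rats were sampled at a later hour is not known. No group had their time since the start without the walking, so time and walking cannot be told apart. An effect of walking itself may be the source and was not tested apart from time.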
